A study of Mus musculus with 9 samples.

How the data were processed

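Total RNA from mouse ear skin, extracted with TRIzol and the RNeasy Plus kit, was labelled with the 3' IVT Express kit and hybridised to Affymetrix arrays, per the labels' protocols. The deposited values are intensities on a linear scale, 1 MAS5 signal per probe set and array. Per the submitters' processing notes they were made with MAS5 and the Affymetrix Expression Console; versions and settings are not given in the sources used here. The value tables do not state their scaling, but leaving out the highest and lowest 2% of probe sets gave a mean of 250.001 in each array, so each array had been scaled to one target. The minimum was above 0 and the maximum between 19986 and 31242, so the values were not logarithms. The median signal was 75.4, 71.2 and 84.0 in vehicle replicates 1 to 3, 86.3, 72.7 and 74.2 in the DNFB replicates, and 81.4, 84.2 and 81.8 in the BAC replicates. Detection calls, scan dates and batches were not used here, so background could not be separated from low signal array by array. Group and replicate came from the sample titles. No 2 arrays held identical values.

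Of the probe sets, 64 were control probe sets, which were left out of the tests. The platform annotation gave 34945 probe sets 1 gene symbol and 932 several, and 9160 were not listed with a gene and are unnamed here. Of the probe sets with 1 gene, 34741 matched a gene identifier in RefSeq GRCm38.p6, which was used for names only, and 0 symbols changed through it. A gene was represented by the probe set with the highest mean log2 value over the 9 arrays, giving 18193 genes; 9010 genes had several probe sets. Genes were tested when their value lay above the 40th percentile of the array in at least 3 of the 9 arrays, which left 14122. Another tested probe set of the same gene was called in the opposite direction for 7 of the genes changed in DNFB against vehicle, 10 in BAC against vehicle and 3 in DNFB against BAC.

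Signals were transformed as log2(signal + 16), so that a log2 change understates the change of dim genes. All 9 arrays entered one linear model with a mean per treatment, fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend; 6 residual and 9.09 prior degrees of freedom). DNFB was compared with the vehicle, BAC with the vehicle and DNFB with BAC, two-sided, and a moderated F test covered differences among the 3 treatments. P-values were adjusted by the Benjamini-Hochberg method over the tested genes of a comparison, with a threshold of 0.05. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so none was run for single genes.

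Gene lists of pathways and cell type markers, 36 in all, were fixed before the data were examined, and the 33 with at least 3 tested genes were tested. The lists left out for too few tested genes were eosinophil and basophil markers, red blood cell genes and sex-specific genes. Each list was compared with all other tested genes by camera with a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 33 lists of a comparison. The test was repeated with the correlation estimated from the data. Counts of members higher or lower come from the limma test over all tested genes, and counts "adjusted over the list alone" from an adjustment within the list. The rule for named genes was also fixed beforehand. It took, per comparison, the 8 largest rises and 8 largest falls among genes past the threshold whose arrays did not overlap between the groups and whose higher group mean lay above the median of the tested genes. It added up to 3 members with the largest change from each list, or the member with the smallest p where none passed, and a set of genes reported whatever their values: Il1b, Il6, Tnf, Cxcl1, Cxcl2, Cxcl10, Ccl2, Ptgs2, Hmox1, Nqo1, Cd207 and Krt6a. Other members of lists, and genes repeated from another comparison, are given beside these where the text needs them and were chosen after their values were seen.

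The overlap of the comparisons with the vehicle was set beside independent lists of the same sizes. It was also set beside 100 simulations in which unchanged groups were compared with shared simulated vehicle arrays. The procedure was tested on simulated data with known changes in the 14122 genes. For DNFB against vehicle it recovered 31.3% of 1.5-fold, 65.7% of 2-fold and 93.9% of 4-fold changes and called 4 of 13892 unchanged genes. For BAC against vehicle it recovered 41.8%, 67.2% and 97.0% at the same sizes and called 11 of 13922 unchanged genes, and for DNFB against BAC 37.3%, 73.9% and 97.7%, with 19 of 13692 unchanged genes called. In each comparison with the vehicle 67, 67 and 66 genes were changed at these sizes, far fewer than were called in the real arrays. Recovery depends on that number, so these rates need not hold there. The noise was normal with the SDs of the limma fit, so the low count of false calls was partly built in. A list given a simulated rise after DNFB was found (adjusted p = 5.04e-30 in DNFB against vehicle), and 0 of 33 random lists were called. The simulated genes varied independently, so this does not show the error rate for lists whose genes vary together. In other splits of the real arrays up to 13, 16 and 17 of the 33 gene lists were shifted, in the order of the 3 comparisons. These splits kept part of the real difference between the groups, so they do not show the rate of false calls either.

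The alternatives were a pseudocount of 1 or 64, no filter or a filter at the 60th percentile, quantile normalization, centring each array on its median, eBayes without a trend, the replicate number as a block, leaving out each array in turn, fitting only the arrays compared, all probe sets in place of 1 per gene, the mean of a gene's probe sets, a 2-fold minimum and, for lists, the estimated correlation. Centring on the median was added for the named genes after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.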

Results

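The series measured mRNA in ear skin of C57BL/6 mice 6 h after compounds were applied to the surface of the ear. Each of 3 treatments had 3 arrays: DNFB, which the labels call an allergen; BAC, which they call an irritant; and the vehicle, acetone with olive oil. Per the labels, the compounds went on the right ear and the vehicle on the left, so the side of the ear went with the treatment. The doses are not given in the sources used here. The labels number the replicates but do not say that they came from separate animals; p-values therefore measure the spread between these samples, which may be technical. Each array gave a MAS5 signal per probe set. The trimmed mean signal was 250.001 in each array and the median signal lay between 71.2 and 86.3. Across all probe sets other than controls, arrays of the same group correlated with r from 0.935 to 0.966 in 9 pairs. Arrays of different groups correlated with r from 0.925 to 0.948 in 27 pairs. The ratio of the 3' to the 5' Gapdh control signal, a measure of RNA integrity, was between 0.856 and 0.880 in the vehicle arrays, and between 0.917 and 0.932 in the BAC arrays. It was 0.841, 1.36 and 0.943 in DNFB replicates 1 to 3. The ratio for actin was 1.05, 1.05 and 1.10 in the vehicle arrays, 1.09, 1.28 and 1.23 in the DNFB arrays and 1.18, 1.22 and 1.19 in the BAC arrays. Both ratios were higher in every BAC array than in every vehicle array. Arrays carry no read depth, and their number limits the precision of each value. Signals below are given as mean ± SD over 3 arrays, and log2 changes with their standard error (SE) from limma.

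The comparison of DNFB with the vehicle asked how ear skin responded to the allergen. The cytokine gene Il6 and the stress genes Srxn1, Atf3 and Hsph1 were among the largest rises. Of 37 cornified envelope and barrier genes 25 fell. Among 22 fatty acid and sebaceous lipid genes 10 fell and 1 rose, and among 19 cholesterol synthesis genes 7 rose and 1 fell. Il6 (Entrez gene 16193), which encodes the cytokine interleukin-6, rose from a signal of 120 ± 44.6 to 2218 ± 561, a log2 change of 4.07 ± 0.21 (SE), with a limma adjusted p of 1.38e-08. Srxn1 (Entrez gene 76650), encoding sulfiredoxin, which restores oxidised peroxiredoxins, rose from 536 ± 183 to 5912 ± 1739 (log2 change 3.44 ± 0.21). Atf3, a transcription factor induced by stress, rose from 583 ± 126 to 5533 ± 144 (log2 change 3.23 ± 0.13), and Hsph1, a heat shock protein of the Hsp110 family, from 244 ± 27.9 to 2202 ± 266 (log2 change 3.09 ± 0.17). The other large rises were in Nr4a3, an orphan nuclear receptor (log2 change 3.05 ± 0.13), Nts, which encodes neurotensin (2.99 ± 0.19), and S100a9 and S100a8, the subunits of calprotectin (3.03 ± 0.50 and 2.88 ± 0.46). Vehicle replicate 2 stood apart in the S100 genes, with an S100a9 signal of 2633 beside 451 and 352 in the other vehicle arrays; without it the changes of S100a9 and S100a8 were 3.92 and 3.68. Among the genes reported whatever their values, Il1b (2.51 ± 0.18), Cxcl1 (2.44 ± 0.25), Cxcl2 (2.23 ± 0.34), Ccl2 (1.44 ± 0.22), Hmox1 (2.71 ± 0.16) and Nqo1 (0.76 ± 0.17) rose. Cxcl10 (0.96 ± 0.36, adjusted p = 0.0911), Ptgs2 (0.39 ± 0.22, adjusted p = 0.289) and Tnf (-0.71 ± 0.48, adjusted p = 0.387) did not pass the limma test. Without 1 array their changes lay between 0.53 and 1.21, 0.14 and 0.65, and -1.15 and -0.46. The DNFB signal of Tnf lay below the 40th percentile in 3 of 3 arrays. Its change was -0.98 with a pseudocount of 1 and -0.39 with 64.

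In the list of NRF2 target genes, whose products detoxify oxidants and electrophiles and make glutathione, 17 of 30 rose after DNFB and none fell (21 adjusted over the list alone), led by Srxn1, Osgin1 (2.87 ± 0.21) and Hmox1, the haem-degrading enzyme. The list was shifted up against other genes (camera adjusted p = 4.58e-16, and adjusted p = 0.0779 with an estimated correlation). Of 20 heat shock and proteotoxic stress genes, 15 rose and none fell (15 adjusted over the list alone), including Hsph1, Hspa1a (2.45 ± 0.13) and Dnajb1 (1.65 ± 0.11), which encode chaperones. That shift had an adjusted p of 4.58e-16 and held with an estimated correlation (adjusted p = 0.0371). In the unfolded protein and integrated stress response list, 14 of 24 rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 2.8e-11, and adjusted p = 0.0779 with an estimated correlation). Its members Ppp1r15a, a regulatory subunit of a phosphatase for eIF2alpha, and Ddit3, the transcription factor CHOP, rose by 2.44 ± 0.14 and 2.12 ± 0.20. Of 26 AP-1 and immediate early genes, 20 rose and 1 fell (21 and 2 adjusted over the list alone; adjusted p = 1.9e-18, and adjusted p = 0.0371 with an estimated correlation), with Atf3, Maff (2.81 ± 0.12) and Egr1 (1.92 ± 0.12), which encode transcription factors, among the rises.

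Among inflammatory groups, 13 of 27 chemokine genes rose after DNFB and 1 fell (14 and 2 adjusted over the list alone; adjusted p = 0.000327, and adjusted p = 0.254 with an estimated correlation). The gene that fell was Ccl20, a chemoattractant for cells bearing CCR6, at -2.06 ± 0.43. Neutrophil markers rose in 10 of 19 cases and fell in none (13 adjusted over the list alone; adjusted p = 8.67e-09, and adjusted p = 0.0779 with an estimated correlation), with Clec4d, a C-type lectin receptor, at 2.22 ± 0.22. Of 24 inflammatory cytokine genes, 7 rose and 3 fell (9 and 3 adjusted over the list alone; adjusted p = 0.0101, and adjusted p = 0.227 with an estimated correlation); the shift had an adjusted p of 0.0821 without DNFB replicate 1. NF-kB feedback and adhesion genes went both ways, with 5 of 19 higher and 2 lower (6 and 3 adjusted over the list alone; adjusted p = 0.0292, and adjusted p = 0.574 with an estimated correlation). This shift did not pass without vehicle replicate 3 (adjusted p = 0.16), without DNFB replicate 1 (0.0821), without the intensity trend (0.0674) or with the mean of a gene's probe sets (0.245). Socs3, an inhibitor of cytokine signalling, rose by 2.47 ± 0.21 and Nfkbiz, a nuclear IkB protein, by 1.30 ± 0.10, while Tnfaip3, the NF-kB inhibitor A20, and Nfkbia, the inhibitor IkB-alpha, fell by 1.05 ± 0.16 and 0.63 ± 0.10. Of 32 interferon-stimulated genes, 2 rose and none fell (1 adjusted over the list alone; adjusted p = 0.0101, and adjusted p = 0.0839 with an estimated correlation), Rtp4 by 0.95 ± 0.22.

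In the cornified envelope and barrier list, 25 of 37 genes fell after DNFB and none rose (28 fell and 1 rose adjusted over the list alone; adjusted p = 2.05e-18, and adjusted p = 0.0839 with an estimated correlation). The late cornified envelope genes Lce1h (-1.52 ± 0.13), Lce1m (-1.49 ± 0.14) and Lce1d (-1.41 ± 0.13), structural proteins of the barrier, fell most among its members. Of 22 fatty acid and sebaceous lipid genes, 10 fell and 1 rose (12 and 2 adjusted over the list alone; adjusted p = 0.000482, and adjusted p = 0.197 with an estimated correlation), among them the fatty acid elongases Elovl4 (-1.40 ± 0.11) and Elovl3 (-0.82 ± 0.17). The largest falls among genes past the threshold, without overlap between the arrays and with a higher group mean above the median gene, were in Rnase2b (Entrez gene 54159), of the ribonuclease A family, at -2.17 ± 0.16 (adjusted p = 5.04e-07), Fen1, a flap endonuclease (-2.15 ± 0.43), Ccl20, Gramd1c (-1.99 ± 0.16), and Ereg, the growth factor epiregulin, whose signal fell from 2679 ± 187 to 698 ± 114 (-1.93 ± 0.15). Lce1l (-1.81 ± 0.16), the elongase Elovl7 (-1.75 ± 0.14) and the adhesion gene Nectin1 (-1.74 ± 0.42) followed. The Nectin1 call ended without vehicle replicate 3 (-1.54, adjusted p = 0.0606) and with the mean of its probe sets (-0.83, adjusted p = 0.135). Without DNFB replicate 1 its change was -1.11. Krt6a, a keratin of activated epidermis, fell by 0.96 ± 0.20, and Cd207, which encodes langerin, a marker of Langerhans cells, by 0.93 ± 0.21.

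Markers of other cell types moved with DNFB as well. Of 21 skeletal muscle markers, 9 rose and none fell (14 adjusted over the list alone; adjusted p = 6.09e-07, and adjusted p = 0.456 with an estimated correlation), with a median log2 change of 0.47. Of 15 fibroblast and matrix genes, 4 rose and none fell (10 adjusted over the list alone; adjusted p = 3.33e-05, and adjusted p = 0.227 with an estimated correlation), Mfap5, a microfibril protein, by 0.77 ± 0.11. Of 15 endothelial markers, 2 rose and none fell (3 adjusted over the list alone; adjusted p = 0.00134, and adjusted p = 0.254 with an estimated correlation), Vwf, the von Willebrand factor, by 0.93 ± 0.19. Monocyte and macrophage markers rose in 4 of 18 cases (4 adjusted over the list alone; adjusted p = 0.0376, and adjusted p = 0.488 with an estimated correlation), Cd14 by 0.79 ± 0.17 and Cd68 by 0.58 ± 0.13. That shift did not pass without vehicle replicate 1 (adjusted p = 0.0501), vehicle replicate 3 (0.171) or DNFB replicate 3 (0.154), after quantile normalization (0.0693) or with the filter at the 60th percentile (0.0519). Activated and wounded keratinocyte genes had 8 members higher and 6 lower of 27 (9 and 6 adjusted over the list alone). The list was not shifted (adjusted p = 0.517, and adjusted p = 0.826 with an estimated correlation) except without vehicle replicate 2 (0.0358 with the preset correlation).

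In all, 1955 of 14122 tested genes differed between DNFB and the vehicle by limma at an adjusted threshold of 0.05, 955 higher and 1000 lower, of which 240 and 205 by at least 2-fold. The arrays of the groups did not overlap in 4357 genes, or 30.85%, where chance gives 10%. The count was 1280 without vehicle replicate 1, 1254 without vehicle replicate 3 and 1202 without the intensity trend. With each array centred on its median, 1235 genes were higher and 816 lower, or 60.2% higher beside 48.9% in the deposited scaling. Of 33 lists, 18 were shifted, 16 up and 2 down, and 2 held with an estimated correlation.

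**Figure D1:**
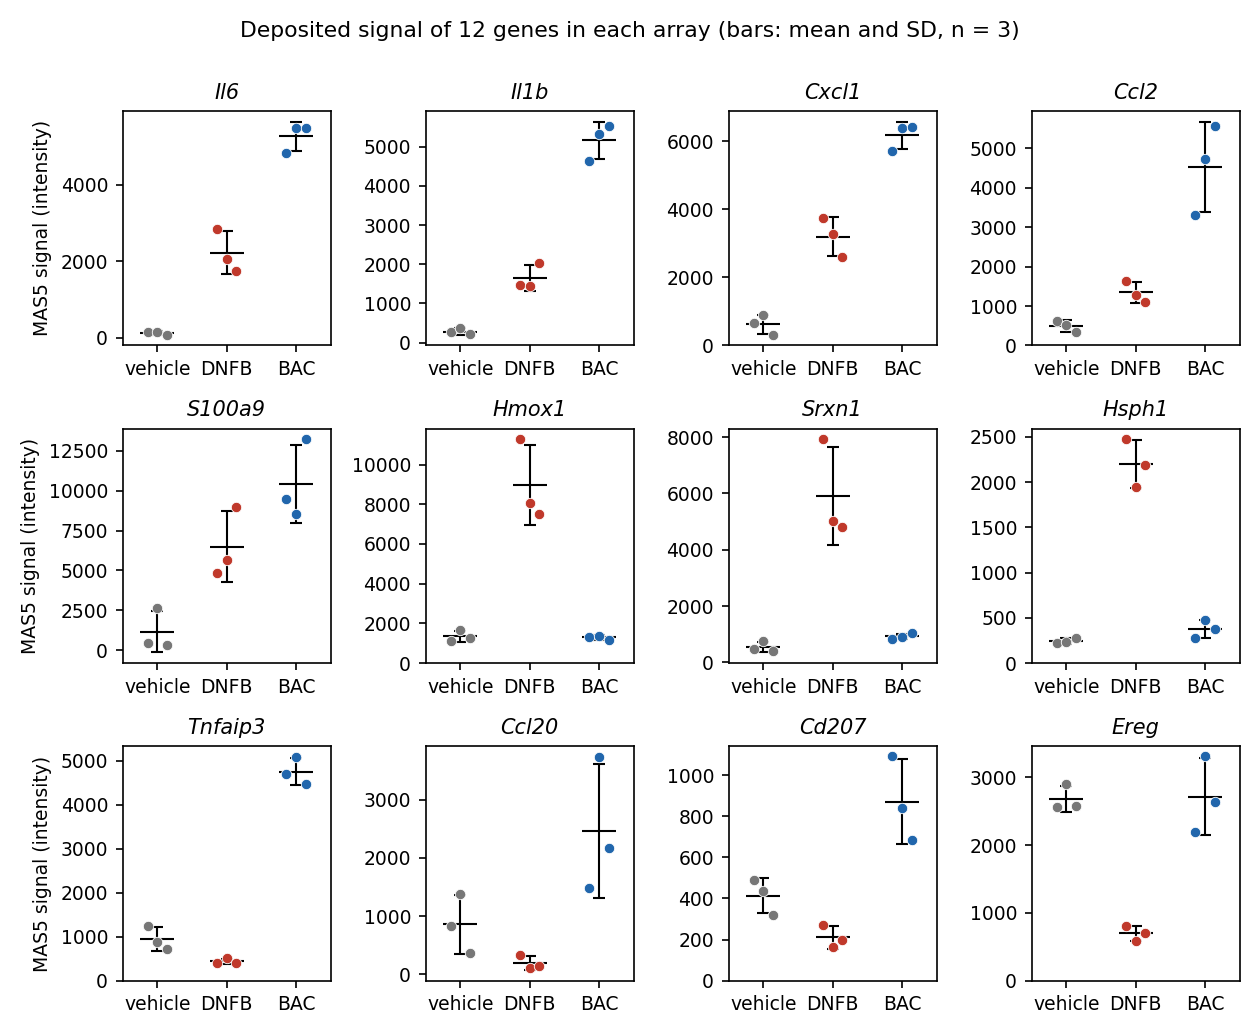
Deposited MAS5 signal (linear scale, intensity units) of 12 genes in each of the 9 arrays. Points are arrays, horizontal lines group means and error bars the SD over 3 arrays. Il6 averaged 120 in vehicle, 2218 in DNFB and 5273 in BAC arrays, whereas Hmox1 averaged 1351, 8966 and 1290.

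The comparison of BAC with the vehicle asked how ear skin responded to the irritant. The cytokine genes Il6 and Il1b and the chemokine gene Cxcl2 were among the largest rises, and 22 of 37 cornified envelope and barrier genes fell. Il6 rose from 120 ± 44.6 to 5273 ± 380 (log2 change 5.34 ± 0.21, limma adjusted p = 5.53e-10) and Il1b (Entrez gene 16176), interleukin-1 beta, from 280 ± 81.6 to 5164 ± 474 (4.16 ± 0.18). Ptx3, a secreted pentraxin of innate immunity, rose from 265 ± 72.6 to 4073 ± 1236 (3.85 ± 0.22), Rgs16, a regulator of G protein signalling, from 36.3 ± 23.2 to 692 ± 73.8 (3.85 ± 0.27), and Adamts4, a protease of the matrix, from 81.9 ± 3.95 to 1348 ± 269 (3.78 ± 0.19). The vehicle signal of Rgs16 lay below the 40th percentile in 2 of 3 arrays, so its change rests on the pseudocount: it was 4.41 with a pseudocount of 1 and 2.94 with 64. Cxcl2, a neutrophil chemoattractant, rose by 3.79 ± 0.34, S100a9 by 3.74 ± 0.50 and S100a8 by 3.58 ± 0.46. Without vehicle replicate 2 the S100 changes were 4.63 and 4.37. Cxcl1 (3.40 ± 0.25), Ccl2 (3.17 ± 0.22), Cxcl10 (3.06 ± 0.36), Cd207 (1.04 ± 0.21) and Krt6a (0.72 ± 0.20) also rose. The vehicle signal of Cxcl10 was as low in 2 of 3 arrays, and its change was 3.66 with a pseudocount of 1 and 2.21 with 64. Krt6a passed narrowly (adjusted p = 0.0284) and did not pass without vehicle replicate 1 (0.0716), vehicle replicate 2 (0.0532), vehicle replicate 3 (0.0815), BAC replicate 1 (0.093) or BAC replicate 2 (0.135). Tnf (0.82 ± 0.48, adjusted p = 0.286), Ptgs2 (0.22 ± 0.22, adjusted p = 0.568), Hmox1 (-0.05 ± 0.16, adjusted p = 0.881) and Nqo1 (-0.35 ± 0.17, adjusted p = 0.183) did not pass. Without 1 array Tnf lay between 0.38 and 1.19, Ptgs2 between -0.03 and 0.48 and Hmox1 between -0.17 and 0.11, and with the mean of its probe sets Ptgs2 was 0.72 (adjusted p = 0.0273).

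All but 1 of the 19 NF-kB feedback and adhesion genes rose after BAC: 18 rose and none fell (19 adjusted over the list alone; adjusted p = 5.19e-26, and adjusted p = 0.0284 with an estimated correlation). Its largest changes were in Socs3 (3.08 ± 0.21), Sele, the endothelial adhesion molecule E-selectin (2.86 ± 0.23), and Rel, an NF-kB subunit (2.34 ± 0.21); Tnfaip3 rose by 2.34 ± 0.16. Of 27 chemokine genes, 18 rose and none fell (20 adjusted over the list alone; adjusted p = 2.84e-18, and adjusted p = 0.0305 with an estimated correlation), with Ccl7, a monocyte chemoattractant, at 3.42 ± 0.27. Of 24 inflammatory cytokine genes, 7 rose and 2 fell (11 and 2 adjusted over the list alone; adjusted p = 9.41e-06, and adjusted p = 0.0667 with an estimated correlation), with Csf3, the granulocyte colony-stimulating factor, at 3.08 ± 0.35. The vehicle signal of Csf3 lay below the 40th percentile in 3 of 3 arrays, and its change was 3.84 with a pseudocount of 1 and 2.12 with 64. Of 26 AP-1 and immediate early genes, 22 rose and none fell (24 adjusted over the list alone; adjusted p = 1.11e-32, and adjusted p = 0.0143 with an estimated correlation), including Atf3 (3.49 ± 0.13), Zfp36, a protein that destabilises cytokine mRNA (2.63 ± 0.15), and Jun (2.52 ± 0.13). Of 32 interferon-stimulated genes, 9 rose and none fell (13 adjusted over the list alone; adjusted p = 4.93e-07, and adjusted p = 0.0143 with an estimated correlation), among them the transcription factor Irf1 (1.41 ± 0.12) and Rtp4 (1.31 ± 0.22).

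Cell markers moved as well. Of 19 neutrophil markers, 13 rose and none fell (13 adjusted over the list alone; adjusted p = 2.62e-14, and adjusted p = 0.0284 with an estimated correlation), with Csf3r, the receptor of granulocyte colony-stimulating factor, at 3.11 ± 0.21. Monocyte and macrophage markers rose in 7 of 18 cases and fell in none (7 adjusted over the list alone; adjusted p = 2.77e-05, and adjusted p = 0.167 with an estimated correlation), including Cd14 (1.58 ± 0.17) and Ccr2, a chemokine receptor of monocytes (1.14 ± 0.23). Langerhans and dendritic cell markers rose in 5 of 16 cases and fell in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.000782, and adjusted p = 0.217 with an estimated correlation), including Cd83, a marker of mature dendritic cells (1.82 ± 0.16), Cd207 and the lectin Cd209a (0.73 ± 0.15). Skeletal muscle markers were shifted up as a list (median log2 change 0.33, adjusted p = 0.000369, and adjusted p = 0.497 with an estimated correlation) although 0 of 21 passed the limma test, and 0 adjusted over the list alone. An unadjusted p under 0.05 was found in 6 of them. Without BAC replicate 3 the median was 0.16 and the shift did not pass (adjusted p = 0.0824). The endothelial list (3 of 15 higher, 3 adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.325 with an estimated correlation) and the fibroblast and matrix list (1 of 15 higher, 0 adjusted over the list alone; adjusted p = 0.0102, and adjusted p = 0.389 with an estimated correlation) were shifted up too. The fibroblast shift did not pass without vehicle replicate 2 (adjusted p = 0.0863), without BAC replicate 1 (0.135) or after quantile normalization (0.0902).

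In the cornified envelope and barrier list, 22 of 37 genes fell after BAC and none rose (23 adjusted over the list alone; adjusted p = 8.72e-10, and adjusted p = 0.188 with an estimated correlation). Cdsn, corneodesmosin (-1.26 ± 0.26), Flg, filaggrin (-1.16 ± 0.24), and the desmosomal cadherin Dsc1 (-1.11 ± 0.15) fell most among them. Activated and wounded keratinocyte genes rose in 11 of 27 cases and fell in 1 (12 and 1 adjusted over the list alone; adjusted p = 4.94e-06, and adjusted p = 0.233 with an estimated correlation), including Lcn2, an antimicrobial lipocalin (1.98 ± 0.23). The fatty acid and sebaceous lipid list had 2 members higher and 3 lower of 22 (3 and 3 adjusted over the list alone) and no shift (adjusted p = 0.495). The NRF2 target genes had 6 members higher and 3 lower of 30 (6 and 3 adjusted over the list alone) and no shift (adjusted p = 0.64); their median log2 change was -0.05 where the mean, 0.07, and the test pointed up. Osgin1 rose by 1.74 ± 0.21. Heat shock and proteotoxic stress genes rose in 8 of 20 cases and fell in 1 (9 and 1 adjusted over the list alone; adjusted p = 2.77e-05, and adjusted p = 0.13 with an estimated correlation), Cryab, a small heat shock protein, by 0.97 ± 0.14. Unfolded protein and integrated stress response genes rose in 11 of 24 cases and fell in 1 (13 and 2 adjusted over the list alone; adjusted p = 2.28e-06, and adjusted p = 0.142 with an estimated correlation), Chac1, a glutathione-degrading enzyme, by 2.27 ± 0.23.

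By the same criteria, the largest falls after BAC were in Dlx6, a homeobox transcription factor (-2.22 ± 0.33, adjusted p = 0.000314), and Lce3f, of the late cornified envelope family (-1.76 ± 0.35). The BAC signal of Dlx6 lay below the 40th percentile in 2 of 3 arrays, and its change was -2.56 with a pseudocount of 1 and -1.63 with 64. Malat1, a nuclear long non-coding RNA, followed at -1.69 ± 0.35. Another probe set of Malat1 was called in the opposite direction, and its call ended with the mean of all its probe sets (-0.21, adjusted p = 0.502). Sema4b (-1.62 ± 0.20), Tmem242 (-1.55 ± 0.27), Defb6, a beta-defensin (-1.51 ± 0.19), Fut2, a fucosyltransferase (-1.51 ± 0.24), and Polr3g, a subunit of RNA polymerase III (-1.49 ± 0.20), came next. In all, 2009 of 14122 genes differed between BAC and the vehicle by limma, 930 higher and 1079 lower, of which 357 and 135 by at least 2-fold. The groups did not overlap in 4822 genes, or 34.15%, beside 10% by chance. The count was 1231 without vehicle replicate 1 (657 higher and 574 lower), 1369 without BAC replicate 2 (655 and 714) and 1364 without BAC replicate 3 (683 and 681). With each array centred on its median, 1139 genes were higher and 734 lower, or 60.8% higher beside 46.3% in the deposited scaling. Of 33 lists, 19 were shifted, 18 up and 1 down, and 5 held with an estimated correlation.

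**Figure D2:**
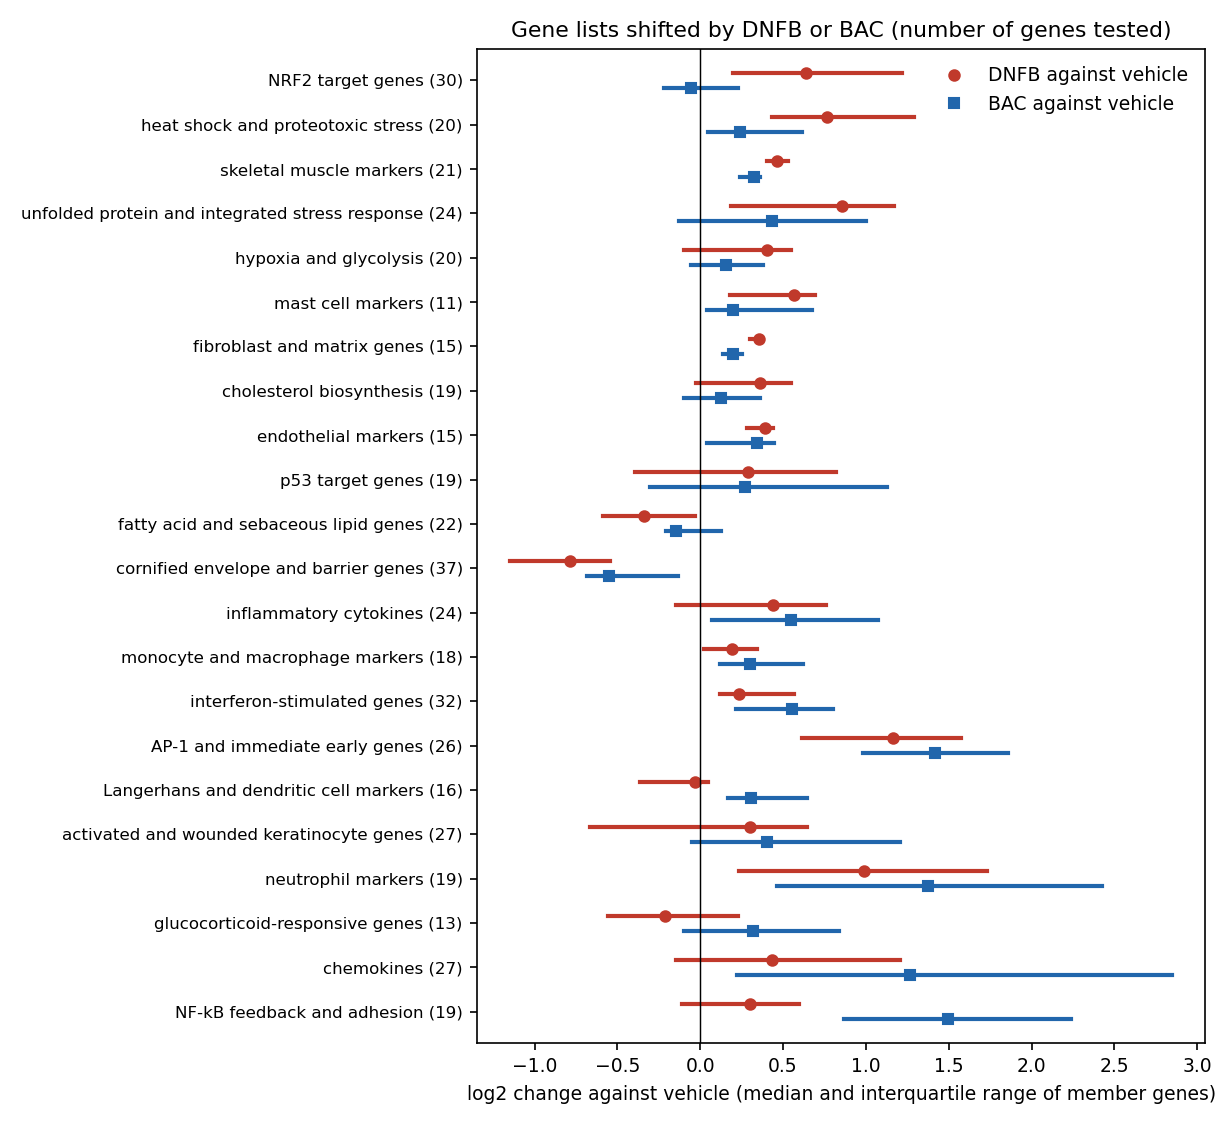
Log2 change against the vehicle of the member genes of 22 gene lists that were shifted in at least 1 of the comparisons with the vehicle, with the number of tested genes in brackets. Points are medians and lines interquartile ranges over genes, for DNFB (circles) and BAC (squares). The median of the NRF2 target genes was 0.64 for DNFB and -0.05 for BAC, and that of the chemokine genes 0.44 and 1.27.

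The direct comparison of DNFB with BAC asked in which genes the responses to the allergen and the irritant differed. After DNFB, 15 of 30 NRF2 target genes and 10 of 20 heat shock and proteotoxic stress genes were higher than after BAC. Of the chemokine genes, 14 of 27 were lower, and of the inflammatory cytokine genes, 5 of 24. With an estimated correlation, 0 of the 19 list shifts held; the adjusted p was 0.0567 for the NRF2, heat shock and chemokine lists and 0.128 for the cytokine list. Hmox1 (Entrez gene 15368) had a signal of 8966 ± 2034 after DNFB and 1290 ± 111 after BAC (log2 difference 2.76 ± 0.16, limma adjusted p = 1.6e-07). Srxn1 (2.63 ± 0.21), Hsph1 (2.51 ± 0.17), Hspa1a (1.92 ± 0.13), Sertad1, a transcriptional coregulator (1.60 ± 0.12), and Procr, the endothelial protein C receptor (1.49 ± 0.16), were higher after DNFB. So were Gclm and Gclc, the subunits of the enzyme that starts glutathione synthesis (2.41 ± 0.16 and 1.84 ± 0.13). Of 30 NRF2 target genes, 15 were higher after DNFB and none lower (20 adjusted over the list alone; adjusted p = 4.33e-19, and adjusted p = 0.0567 with an estimated correlation). Of 20 heat shock and proteotoxic stress genes, 10 were higher and none lower (14 adjusted over the list alone; adjusted p = 1.98e-11, and adjusted p = 0.0567 with an estimated correlation). The unfolded protein and integrated stress response had 6 of 24 genes higher and 2 lower (9 and 2 adjusted over the list alone; adjusted p = 0.0105, and adjusted p = 0.292 with an estimated correlation), with Ppp1r15a at 1.43 ± 0.14. This shift did not pass without DNFB replicate 1 (adjusted p = 0.136) or BAC replicate 1 (0.0943).

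Ccl20 was lower after DNFB than after BAC, with signals of 189 ± 119 and 2465 ± 1155 (log2 difference -3.65 ± 0.43, adjusted p = 8.13e-05), and so were Tnfaip3 (-3.39 ± 0.16), Epgn, an epidermal growth factor receptor ligand (-3.11 ± 0.24), Sele (-2.94 ± 0.23) and Cd83 (-2.68 ± 0.16). Arc (-2.39 ± 0.16), the chemokine Cxcl3 (-2.24 ± 0.29) and the acute phase gene Saa3 (-2.21 ± 0.24) followed. Il1b (-1.65 ± 0.18), Il6 (-1.27 ± 0.21), Ccl2 (-1.73 ± 0.22), Cxcl10 (-2.10 ± 0.36), Cd207 (-1.97 ± 0.21) and Krt6a (-1.68 ± 0.20) were lower after DNFB than after BAC, and Nqo1 was higher (1.11 ± 0.17). Cxcl1 (-0.96 ± 0.25, adjusted p = 0.0317) passed with all arrays but not without DNFB replicate 2 (0.0821), DNFB replicate 3 (0.131), BAC replicate 1 (0.0595), BAC replicate 2 (0.1) or BAC replicate 3 (0.0917). Cxcl2 (-1.56 ± 0.34, adjusted p = 0.013) did not pass without DNFB replicate 1 (0.0511) or BAC replicate 2 (0.0598). Tnf (-1.53 ± 0.48, adjusted p = 0.0684) and Ptgs2 (0.17 ± 0.22, adjusted p = 0.702) did not pass. Tnf passed without vehicle replicate 3 (0.0443), an array outside this comparison, with its change still at -1.53. The DNFB signal of Tnf lay below the 40th percentile in 3 of 3 arrays. Its change was -2.015 with a pseudocount of 1 and -0.92 with 64.

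Of the NF-kB feedback and adhesion genes, 14 of 19 were lower after DNFB than after BAC and none higher (16 adjusted over the list alone; adjusted p = 1.43e-24, and adjusted p = 0.0567 with an estimated correlation). Chemokine genes were lower in 14 of 27 cases (16 lower and 1 higher adjusted over the list alone; adjusted p = 2.47e-15, and adjusted p = 0.0567 with an estimated correlation), among them Ccl11, eotaxin (-2.19 ± 0.21). Inflammatory cytokine genes were lower in 5 of 24 (8 adjusted over the list alone; adjusted p = 0.00142, and adjusted p = 0.128 with an estimated correlation), with Csf3 at -2.16 ± 0.35 and Osm, oncostatin M, at -1.71 ± 0.19. AP-1 and immediate early genes were higher in 2 and lower in 9 of 26 (3 and 12 adjusted over the list alone; adjusted p = 4.04e-06, and adjusted p = 0.123 with an estimated correlation), with the phosphatase Dusp6 at -1.39 ± 0.13. Interferon-stimulated genes were lower in 2 of 32 (2 adjusted over the list alone; adjusted p = 0.00221, and adjusted p = 0.0567 with an estimated correlation), with Irf1 at -1.13 ± 0.12. Neutrophil markers were lower in 5 of 19 (7 adjusted over the list alone; adjusted p = 1.47e-05, and adjusted p = 0.123 with an estimated correlation), with the chemokine receptor Cxcr2 at -1.29 ± 0.25. Langerhans and dendritic cell markers were lower in 3 of 16 (5 adjusted over the list alone; adjusted p = 6.46e-06, and adjusted p = 0.123 with an estimated correlation), and monocyte and macrophage markers in 4 of 18 (7 lower and 1 higher adjusted over the list alone; adjusted p = 0.00753, and adjusted p = 0.267 with an estimated correlation).

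Activated and wounded keratinocyte genes were lower after DNFB than after BAC in 9 of 27 cases and higher in none (11 adjusted over the list alone; adjusted p = 6.46e-06, and adjusted p = 0.234 with an estimated correlation), led by Ereg (-1.93 ± 0.15), the keratin Krt17 (-1.73 ± 0.16) and Krt6a. Cornified envelope and barrier genes were lower in 11 of 37 (13 lower and 1 higher adjusted over the list alone; adjusted p = 6.47e-06, and adjusted p = 0.267 with an estimated correlation), with Lce1h at -0.92 ± 0.13. Fatty acid and sebaceous lipid genes were lower in 4 of 22 (5 adjusted over the list alone; adjusted p = 0.00265, and adjusted p = 0.223 with an estimated correlation), with Elovl4 at -1.25 ± 0.11. Skeletal muscle markers showed no called difference (median log2 difference 0.23, adjusted p = 0.0559). The list passed without vehicle replicate 1 (0.0461), vehicle replicate 3 (0.0481), DNFB replicate 1 (0.00402) or BAC replicate 3 (2.06e-05, median 0.36). In all, 961 of 14122 genes differed between DNFB and BAC by limma, 444 higher and 517 lower after DNFB, of which 51 and 161 by at least 2-fold. The arrays of the groups did not overlap in 3556 genes, or 25.18%, beside 10% by chance. The count was 602 without DNFB replicate 2 (225 higher and 377 lower), 565 without DNFB replicate 3 (174 and 391), 515 without BAC replicate 2 (211 and 304) and 402 without the intensity trend (137 and 265). Of 33 lists, 19 were shifted, 4 up and 15 down, and 0 held with an estimated correlation, where 10 had an unadjusted camera p under 0.05.

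The responses to DNFB and BAC were then set side by side. Against the vehicle, 492 genes were higher and 490 lower after both compounds, 982 in all, and 23 changed in opposite directions. Independent lists of the same sizes would share 62.9 higher and 76.4 lower genes and 138.8 in opposite directions. Simulated unchanged groups set against shared simulated vehicle arrays gave 0.02, 0.01 and 0 on average. With no changed genes hardly any could be called, so these counts do not show what shared vehicle arrays add to the overlap. Across genes, which are not independent replicates, the log2 changes correlated with Pearson's r of 0.640 and Spearman's rho of 0.599, where simulated unchanged groups gave 0.501 and 0.464. The covariance was 0.148 and the simulated covariance 0.034. Both comparisons used the same 3 vehicle arrays, which are too few to split. The simulations did not hold the real vehicle arrays or the correlation between genes, so part of the excess may come from these arrays. The count of genes changed the same way was 622 without vehicle replicate 1, 633 without vehicle replicate 3 and 572 without the intensity trend. With each array centred on its median, 985 genes changed the same way, 637 higher and 348 lower, or 64.7% higher beside 50.1% in the deposited scaling.

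Of the genes higher after both compounds, 87 were also higher after BAC than after DNFB and 40 higher after DNFB than after BAC. Relative to both other groups, 176 genes were higher and 189 lower after DNFB, and 277 were higher and 139 lower after BAC. The genes that moved in opposite directions comprised 20 that fell after DNFB and rose after BAC, and 3 that rose after DNFB and fell after BAC. The former included Tnfaip3, Nfkbia, Cd83, Cd207, Krt6a, Ccl20 (1.59 ± 0.43 after BAC) and Epgn (-0.95 ± 0.24 after DNFB and 2.15 ± 0.24 after BAC). The fall of Epgn after DNFB did not pass without vehicle replicate 2 (adjusted p = 0.0513) or DNFB replicate 2 (0.0667), and the rise of Ccl20 after BAC did not pass without vehicle replicate 3 (0.107), BAC replicate 2 (0.11) or BAC replicate 3 (0.0609). The latter were Gclc (1.17 ± 0.13 after DNFB and -0.68 ± 0.13 after BAC), Gclm (1.87 ± 0.16 and -0.54 ± 0.16) and Rbbp6 (0.77 ± 0.12 and -0.37 ± 0.12), which was named after its values were seen. The fall of Gclm after BAC had an adjusted p of 0.0308, and of 0.0978 without vehicle replicate 1, 0.0857 without vehicle replicate 3, 0.138 without BAC replicate 2, 0.0513 after quantile normalization, 0.0654 after centring on the median and 0.325 with the mean of its probe sets. The fall of Rbbp6 after BAC (adjusted p = 0.0429) did not pass after quantile normalization (0.0835) or centring on the median (0.109), nor without vehicle replicate 1 (0.101), vehicle replicate 2 (0.127), vehicle replicate 3 (0.0747), DNFB replicate 3 (0.0552), BAC replicate 1 (0.118), BAC replicate 2 (0.062) or BAC replicate 3 (0.0992). With the mean of its probe sets, the change of Rbbp6 after DNFB was -0.10 (adjusted p = 0.742), and neither its fall after BAC (0.0523) nor its difference between the compounds (0.40, adjusted p = 0.162) passed. The count of 23 was 11 without vehicle replicate 1, vehicle replicate 2 or BAC replicate 2, and 9 without the intensity trend. By the moderated F test, 2741 of 14122 genes, or 19.41%, differed among the 3 treatments, and 1635 did so without the intensity trend.

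**Figure D3:**
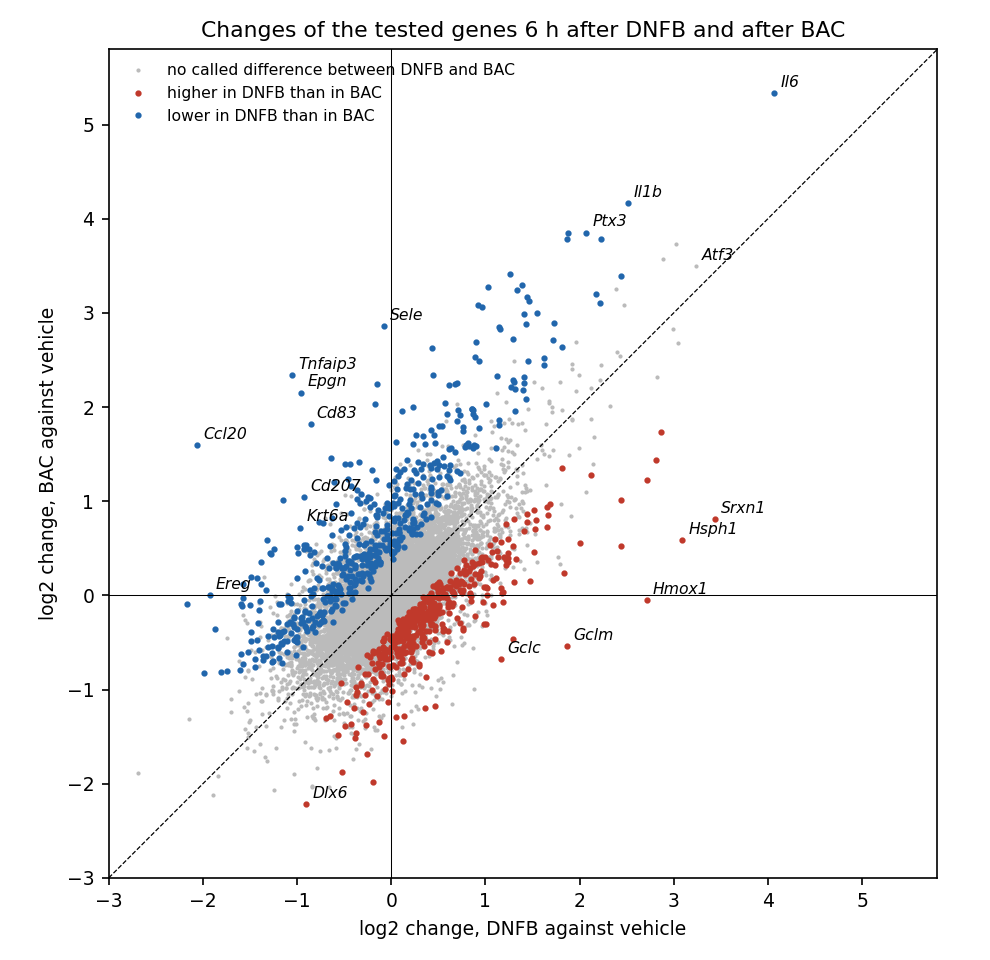
Log2 change of each of the 14122 tested genes after DNFB (horizontal axis) and after BAC (vertical axis), both against the vehicle, with the line of equal change dashed. Colours mark the 444 genes higher and the 517 lower after DNFB than after BAC by limma. Hmox1 and Srxn1 lie below the line of equal change, and Tnfaip3 and Ccl20 lie above it with a fall after DNFB and a rise after BAC.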

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

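The test of the Langerhans and dendritic markers was chosen after the result for their whole list was seen, and the test of the sizes of the differences after quantile normalization after the count of calls kept. The effect of the compound differed in direction between DNFB and BAC for 20 genes that were lower after DNFB and higher after BAC than in the vehicle, and for 3 genes that went the other way, and limma called the difference between DNFB and BAC itself in 23 of 23, which the choice of genes called in opposite directions fixed beforehand; for Rbbp6 it was not called with the mean of its probe sets (adjusted p = 0.162). Scaling of the arrays as the whole source of these differences is argued against by their median size, which was 1.52 after quantile normalization beside 1.54 before, with a median SE of 0.138. Whether scaling added to the opposite calls cannot be told apart: all 23 genes kept both signs after quantile normalization but 15 kept both calls, and in the other 8 the median of the smaller change went from 0.44 to 0.37 while its SE went from 0.126 to 0.130. A part of RNA quality cannot be told apart either: without DNFB replicate 2, the array with the Gapdh ratio of 1.36, 23 genes kept both signs and 19 both calls, but the other DNFB arrays lay on the same side of the vehicle mean in 23 of 23, so the signs were fixed beforehand. A loss of Langerhans and dendritic cells after DNFB could lower Cd207 and Cd83, but the 14 other markers of that list, with median changes of -0.02 after DNFB and 0.24 after BAC, gave a camera p of 0.836 after DNFB and decide neither way; a differing response to the allergen and the irritant, and the unstated doses, stay open and untested.

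Of 4908 tested probe sets that the annotation does not tie to a single gene, and which entered no comparison above, limma called 351 changed in DNFB against vehicle (161 higher and 190 lower), 312 in BAC against vehicle (169 and 143) and 199 in DNFB against BAC (83 and 116).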

How the results depend on the processing

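The settings below were chosen before the data were examined, except centring on the median for the named genes. Of 56 list shifts, 56 kept their call with a pseudocount of 1 or 64 or with centring on the median, 53 with no filter, the stricter filter, quantile normalization or the mean of a gene's probe sets, 52 without an intensity trend, 49 to 55 without 1 array and 7 with an estimated correlation. Of 165 calls of named genes, 165 were kept with a pseudocount of 1 or 64, 162 with quantile normalization, 163 with centring on the median, 158 to 163 without 1 array and, of 163 with a value, 156 with the mean of a gene's probe sets. The 1 reversal was Rbbp6 in DNFB against vehicle, at -0.10 with the mean of its probe sets; the cause was not tested.

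Counts that moved by over 1.5 times are given in the order DNFB against vehicle, BAC against vehicle, DNFB against BAC and F test where all moved. With all probe sets, which counts several for many genes and adds those tied to no single gene, they were 3130, 3045, 1487 and 4407 beside 1955, 2009, 961 and 2741. With a 2-fold minimum they were 445, 492 and 212. Without the intensity trend, DNFB against vehicle gave 1202, DNFB against BAC 402, the F test 1635, genes changed the same way by both compounds 572 and genes changed in opposite directions 9; the cause was not tested. Leaving out 1 array, which leaves fewer samples, gave 1254 to 1927, 1231 to 2149, 515 to 998 and 1835 to 2657 genes, 622 to 894 genes changed the same way and 11 to 25 in opposite directions. With an estimated correlation, 2, 5 and 0 lists were shifted beside 18, 19 and 19. The estimate was 0.298 for the NF-kB, 0.5 for the cholesterol and 0.79 for the muscle list, beside the preset 0.01. For the interferon list it was -0.016, yet its unadjusted camera p in DNFB against vehicle went from 0.0047 to 0.0178. A higher correlation was therefore not the whole cause, and the rest was not tested. Without 1 array, at the preset correlation, 15 to 19, 17 to 20 and 16 to 21 lists were shifted. The covariance of the responses was 0.199 with a pseudocount of 1 and 0.0975 with 64, which raises or lowers the changes of dim genes. Pearson's r stayed between 0.590 and 0.676 without 1 array.

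No pairing by replicate number common to the 3 groups was found. Deviations of arrays with the same number correlated with r from -0.12 to 0.15 across genes, above 0.1 in 1 of 9 pairs, vehicle 1 with BAC 1. Arrays with different numbers gave r from -0.16 to 0.12, and 0 arrays correlated best with their own number in both other groups. With the compounds on the right ear and the vehicle on the left, 1 animal could give a vehicle array and 1 compound array. A match in both other groups, or between DNFB and BAC arrays, could therefore not show a shared animal. With 3 arrays per group these correlations cannot exclude that same-numbered arrays shared an animal. With the replicate block the counts were 1874, 1939 and 860, 2595 by the F test, and 18, 19 and 21 lists. The lists gained were skeletal muscle markers (adjusted p = 0.00875) and inflammasome and pyroptosis genes (adjusted p = 0.0491) in DNFB against BAC; among named genes the fall of Rbbp6 after BAC lost its call (adjusted p = 0.0581). Signal over background was not available per array, so changes of dim genes rest on the pseudocount and the filter.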

Other observations

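The tests of the spread of the hair follicle genes, and of the muscle share, were chosen after those results were seen; the other tests were not. Clock genes moved in both directions. Nfil3, a repressor of clock output, rose by 1.99 ± 0.18 after DNFB and 2.34 ± 0.18 after BAC, and Bhlhe40, a clock repressor, by 1.41 ± 0.15 and 2.32 ± 0.15, while the clock output factor Hlf fell by 1.04 ± 0.20 and 0.97 ± 0.20. Of 17 circadian clock genes, 3 were higher and 6 lower after DNFB (4 and 7 adjusted over the list alone), with no shift (adjusted p = 0.643; median 0.00 above 0, mean -0.01 and test below). After BAC 3 were higher and 1 lower (3 and 4 adjusted over the list alone; adjusted p = 0.594; median -0.05, mean 0.18 and test above). Between DNFB and BAC the list was shifted down (adjusted p = 0.0396, and adjusted p = 0.267 with an estimated correlation), but not without DNFB replicate 1 (0.141), DNFB replicate 2 (0.0829), BAC replicate 1 (0.123) or the intensity trend (0.0892), or with no filter (0.0501). Glucocorticoid-responsive genes were higher in 3 and lower in 4 of 13 cases after DNFB (3 and 4 adjusted over the list alone; adjusted p = 0.459) and higher in 4 after BAC (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.00542, 0.0527 without BAC replicate 1, and adjusted p = 0.265 with an estimated correlation). Cebpd, a transcription factor also induced by cytokines, rose by 0.86 ± 0.12 and 1.97 ± 0.12. Between DNFB and BAC 6 were lower (8 adjusted over the list alone; adjusted p = 2.46e-07, and adjusted p = 0.123 with an estimated correlation). Hypoxia and glycolysis genes were higher in 9 and lower in 1 of 20 after DNFB (9 and 1 adjusted over the list alone; adjusted p = 0.00267, and adjusted p = 0.158 with an estimated correlation) and in 5 and 1 after BAC (5 and 2 adjusted over the list alone; adjusted p = 0.0102, and adjusted p = 0.192 with an estimated correlation), with no shift between the compounds (adjusted p = 0.837). Adm, the vasodilator adrenomedullin, rose by 1.31 ± 0.22 and 2.20 ± 0.22, and Vegfa by 1.19 ± 0.17 and 1.11 ± 0.17. Of 19 p53 target genes, 7 were higher and 3 lower after DNFB (8 and 5 adjusted over the list alone; adjusted p = 0.31), and 8 and 5 after BAC (9 and 5 adjusted over the list alone; adjusted p = 0.0296, 0.105 with the mean of a gene's probe sets, 0.0603 with the filter at the 60th percentile, and adjusted p = 0.217 with an estimated correlation). Gadd45a, a stress-induced gene also induced without p53, rose by 2.53 ± 0.30 after BAC. The compounds did not differ by list (adjusted p = 0.194). Of 19 cholesterol synthesis genes, 7 were higher and 1 lower after DNFB (9 and 1 adjusted over the list alone; adjusted p = 0.00717, 0.13 without DNFB replicate 1, and adjusted p = 0.574 with an estimated correlation). Insig1, which retains the sterol sensor in the endoplasmic reticulum, rose by 0.77 ± 0.16 and the last enzyme of the pathway, Dhcr7, fell by 0.88 ± 0.18. After BAC (adjusted p = 0.0996, but 0.046 without vehicle replicate 2) and between the compounds (0.194, but 0.000415 without DNFB replicate 2) this list was not shifted. These values used the preset correlation of 0.01. The estimated correlation was 0.5, and with it the camera adjusted p over all arrays was 0.716 and 0.765.

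Mast cell markers were higher in 6 of 11 cases after DNFB (6 adjusted over the list alone; adjusted p = 0.00267, and adjusted p = 0.197 with an estimated correlation) and in 2 after BAC (4 adjusted over the list alone; adjusted p = 0.0177, and adjusted p = 0.245 with an estimated correlation). Hdc, the histamine-forming enzyme, which neutrophils and macrophages also express, rose by 2.69 ± 0.25 after BAC, and Cma1, a mast cell chymase, by 0.73 ± 0.14 after DNFB. Between the compounds there was no shift (adjusted p = 0.563; median 0.14 and test above 0, mean -0.04). The inflammasome and pyroptosis list was not shifted (adjusted p = 0.517, 0.562 and 0.0559 in the 3 comparisons), although between the compounds it passed without vehicle replicate 3 (0.0481), DNFB replicate 3 (0.0345) or BAC replicate 1 (0.021). Nlrp3, an inflammasome sensor (1.23 ± 0.17), and Casp4, an inflammatory caspase (1.23 ± 0.21), rose after BAC, and Gsdma, a pore-forming gasdermin, fell by 1.11 ± 0.16 after DNFB and 0.99 ± 0.16 after BAC. T and natural killer cell markers were not shifted after DNFB (adjusted p = 0.59) or BAC (0.259), yet Gzmb, which encodes granzyme B, rose by 1.41 ± 0.25 and 2.99 ± 0.25. Its vehicle signal lay below the 40th percentile in 2 of 3 arrays, and these changes were 1.82 and 3.52 with a pseudocount of 1, and 0.85 and 2.13 with 64. Between the compounds 2 of 15 were lower after DNFB (2 adjusted over the list alone; adjusted p = 0.0282, 0.0858 without DNFB replicate 3, 0.0596 without BAC replicate 2, 0.144 with no filter, and adjusted p = 0.169 with an estimated correlation). The metal-binding metallothioneins Mt1 and Mt2 rose by 1.15 ± 0.14 and 1.08 ± 0.12 after BAC. Their list was not shifted after DNFB (adjusted p = 0.737; median 0.15 and test above 0, mean -0.01) or BAC (0.127). Between the compounds it was lower after DNFB (adjusted p = 0.0396, and adjusted p = 0.169 with an estimated correlation), but not without DNFB replicate 1 (0.104), DNFB replicate 3 (0.0657), BAC replicate 1 (0.0528), BAC replicate 3 (0.0682) or the intensity trend (0.0829), or with no filter (0.0631). The fibroblast and matrix list was higher after DNFB than after BAC (adjusted p = 0.0347, and adjusted p = 0.467 with an estimated correlation), but not without DNFB replicate 1 (0.102), DNFB replicate 2 (0.0757), BAC replicate 2 (0.1), BAC replicate 3 (0.176) or the intensity trend (0.069), after quantile normalization (0.247), with the filter at the 60th percentile (0.0629) or with the mean of a gene's probe sets (0.15). Not shifted were Langerhans and dendritic cell markers after DNFB (adjusted p = 0.382), endothelial markers between the compounds (0.44), and, in the order of DNFB, BAC and their difference, cell cycle genes (0.698, 0.127 and 0.19), B cell markers (0.423, 0.347 and 0.97), melanocyte markers (0.698, 0.725 and 0.977), adipocyte markers (0.363, 0.757 and 0.371), cartilage markers (0.776, 0.959 and 0.941) and Schwann cell and nerve markers (0.356, 0.714 and 0.371). The test and the median differed in sign for melanocyte markers between the compounds and for adipocyte markers after BAC, and the mean and the median for B cell markers between the compounds.

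Hair follicle keratins and associated proteins spread widely within groups. The mean log2 value of the 29 tested genes was 6.19, 7.19 and 7.54 in the vehicle arrays, 7.61, 5.92 and 7.40 in the DNFB arrays and 6.03, 7.55 and 5.78 in the BAC arrays, and the list was not shifted in the 3 comparisons (adjusted p = 0.781, 0.192 and 0.194; after DNFB the median was -0.10 and the mean 0.00). With the preset correlation of 0.01, single arrays decided this. After BAC the list passed without vehicle replicate 1 (0.00632) or BAC replicate 2 (0.000534), and between the compounds without DNFB replicate 2 (0.000367) or BAC replicate 2 (0.000204). The estimated correlation was 0.512, and with it the camera adjusted p over all arrays was 0.939, 0.801 and 0.785. The fits without 1 array were not repeated with it, so these passes may rest on the preset value. Noise of dim probe sets is argued against, as 0 of 10000 random lists of the same size and mean signal had a pooled SD within groups as large as 0.870, their highest being 0.225. Scaling of the arrays is argued against, as the SD was 0.851 after quantile normalization, where random lists reached 0.189. No biological explanation was tested; the stage of the hair cycle and the part of the ear sampled stay open.

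Of 21 skeletal muscle markers, 9 rose after DNFB, and the shift of the list was lost with an estimated correlation (adjusted p = 0.456). The mean log2 value of the 21 genes was 10.82, 10.92 and 11.29 in the vehicle arrays, 11.25, 11.61 and 11.53 in the DNFB arrays and 10.97, 11.31 and 11.65 in the BAC arrays, and its abundant Acta1, skeletal muscle actin, had signals of 7846 ± 731, 10328 ± 143 and 10099 ± 1894, and Tnnc2, a troponin, of 7230 ± 528, 10473 ± 962 and 9016 ± 1606. Scaling of the arrays is argued against as the whole cause, because the median change after DNFB was 0.38 after quantile normalization beside 0.47, although the change of Acta1 itself (0.40, adjusted p = 0.0423) was 0.21 there (adjusted p = 0.284) and had an adjusted p of up to 0.19 without 1 array, as Tnnc2 did at 0.0539 without vehicle replicate 1. A differing share of muscle in the ear samples may underlie the rises: the mean correlation between the genes' residuals within groups was 0.79, where 10000 random lists reached at most 0.416, and 0 of the 21 genes stood in another list. The side of the ear went with the treatment, and a response of muscle to the compounds stays open and untested.

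Other splits of the same arrays were fitted for each count. The 10 splits of 6 arrays into groups of 3 are too few for a share under 0.05; the real split was the 1 with the highest count in each case. It gave 1955, 2009 and 961 genes in DNFB against vehicle, BAC against vehicle and DNFB against BAC, where the highest of the others gave 0, 0 and 11, and 18, 19 and 19 lists, where the highest of the others gave 13, 16 and 17. Each of the others exchanged 1 array between the groups, so it kept part of the real difference and raised the spread within groups. Their counts are therefore not those of unchanged groups. For the F test, 1 of 100 drawn splits of the 9 arrays, the real one, gave 2741 genes and the highest other 778. That share is the smallest that 100 splits can give, so chance is unlikely but not excluded. For genes changed the same way by both compounds, the real split was again the 1 of 100 with the highest count, 982 against 527, so chance is again unlikely. Every split shared 1 control group between its comparisons, so this does not test what the shared vehicle arrays add.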
